A study of Homo sapiens with 2 samples.

How the data were processed

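RNA crosslinked to SOX2 was measured by PAR-CLIP, a method in which cells take up a photoreactive uridine, RNA is crosslinked to protein by long-wave ultraviolet light, and the RNA fragments that come down with the protein are sequenced. Per the labels' protocols, HEK293T cells (a human embryonic kidney line that carries the SV40 large T antigen) were transfected with a FLAG-tagged SOX2 plasmid, given 0.2 mM 4-thiouridine 24 hours later for 16 hours, and irradiated with 0.4 J/cm2 at 365 nm. Lysates were digested with RNase T1, which cuts after guanosine, at 1 U/ml before and 10 U/ml after FLAG immunoprecipitation. Beads were washed with 300 mM and then 500 mM KCl. Per the labels' protocols, small-RNA libraries were amplified with 18 PCR cycles and read as 50 nt single ends. Both libraries belong to 1 group, and the labels describe them as independent experiments with the same protocol. No control library is used here, so background crosslinking and RNA abundance were not measured.

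Each library has its own deposited list of sites, a table of 6 columns without a header: chromosome, start, end, site name, score and strand. The submitters' processing notes name bcl2fastq, Bowtie 1.1.2 and the build hg19. The site caller, its thresholds, the trimming and the treatment of reads that match several places are not given in the sources used here. The deposited score is a whole number of at least 5 per site, with no shared total between the lists. What the score counts is not given in the sources used here; it looks like a number of reads and is called score throughout. Read depth is therefore unknown, and the sum of scores is given in its place. PCR amplification without molecular identifiers would make reads non-independent, so every interval below covers counting error over sites only.

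Positions are given as in the lists, converted to counting from 1. The largest site end on chromosome 1 is 249168105, which lies beyond the last annotated feature of that chromosome in the GRCh38 annotation, so the lists are not on GRCh38. The reference supplied was GRCh38 without a genome sequence. Builds were not mixed and coordinates were not converted, so sites are reported by position, not by gene. For this reason 4 planned results were not run: annotation classes of sites, genes with sites in both replicates, fixed gene lists and base composition.

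Overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. A site was called shared when it had at least 1 nt in common with a site of the other replicate on the same strand. Shares have 95% Wilson intervals. The chance level came from 1000 random placements of each list on the same chromosome and strand, up to the largest site end on that chromosome, and from 1000 placements within 5 kb of each site; p-values from placements are one-sided, and 0.001 is the smallest they can give. Distances were taken between site midpoints. Scores of shared sites were compared on the log10 scale, using the partner with the longest overlap, with Spearman's rho, Pearson's r and two-sided permutation p-values from 100000 resamples; these run across sites, which are not independent replicates. The share of sites per chromosome was compared between lists with Fisher's exact test (scipy 1.17.1), two-sided, with Benjamini-Hochberg adjustment over 25 chromosomes. With 2 libraries of 1 group, such tests compare these libraries and not conditions. The overlap code was tested on simulated data: over 5 simulated lists of 16964 sites with 20% of sites set on replicate 2 sites, it found 20.3%, and a set correlation of 0.7 between log scores was found as 0.68.

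The sites named below were chosen by a rule set before the data were examined: the 10 pairs of overlapping sites with the best mean rank of score in both replicates. Other sites and regions named were chosen after their values were seen, which is said beside them. Alternatives set before the data were examined were a reciprocal overlap of 50%, strand ignored, a gap of up to 50 nt, the sites of each list at or above its median score, replicate 2 thinned to the size of replicate 1 (mean of 100 draws), local placement, removal of the mitochondrial chromosome, merging of touching sites, pairs with exactly 1 partner, score per nt, and leaving out each replicate. Both lists hold sites on chromosomes 1 to 22, X, Y and M and on no other contig.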

Results

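SOX2 is a transcription factor with an HMG-box DNA-binding domain and one of the factors used to reprogram somatic cells to pluripotency. The series concerns a putative RNA-binding motif of the protein, and this part of it asked where SOX2 contacts RNA. The data were 2 lists of PAR-CLIP sites from HEK293T cells expressing FLAG-tagged SOX2. Replicate 1 held 16964 sites and replicate 2 held 55830 sites, 3.29-fold more. The scores summed to 5365592 in replicate 1 and 5192778 in replicate 2. Sites were short: the median length was 16 nt in replicate 1 and 17 nt in replicate 2, and the shortest was 14 nt in both. The longest site measured 54 nt in replicate 1 and 412 nt in replicate 2. The median score was 26 in replicate 1, with quartiles of 15 and 58, and 19 in replicate 2, with quartiles of 12 and 37. Sites lay on both genomic strands, with 51.7% ± 0.28 (SD, n = 2) on the plus strand.

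A few sites carried much of the signal in both lists. The strongest site took 29.1% of the score sum in replicate 1 and 13.5% in replicate 2, and it was the same site on chromosome 6 in both. The 10 strongest sites together took 47.1% ± 17.7 (SD, n = 2) of the score sum, with 59.7% in replicate 1 and 34.6% in replicate 2. The numbers of strong sites differed little: 268 sites in replicate 1 and 274 in replicate 2 had scores of at least 1000. At a score of at least 100 the numbers were 2518 and 4096, a ratio of 1.63, and at a score of at least 10 they were 16852 and 51845, a ratio of 3.08. The larger number of sites in replicate 2 was thus found among low scores.

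The comparison the design holds is between the 2 experiments. Of the sites in replicate 1, 3621 (21.3%, 95% Wilson interval 20.7 to 22.0) overlapped a site of replicate 2 on the same strand. These shared sites carried 75.5% of the score sum of replicate 1. Much of this lay in few sites: the highest-scoring ones, on chromosomes 6 and 2, were shared and took 29.1% and 13.65% of that sum. Of the sites in replicate 2, 3627 (6.50%, interval 6.30 to 6.70) overlapped a site of replicate 1, and they carried 51.2% of its score sum. On the opposite strand, 35 sites of replicate 1 overlapped a site of replicate 2, or 0.206%. Sites of replicate 1 placed at random on their chromosome and strand overlapped in 0.18% of cases on average and in 0.277% at most (permutation test over 1000 placements, one-sided, p = 0.001). Most of that chance overlap fell on the small mitochondrial chromosome. On the nuclear chromosomes, 21.1% of replicate 1 sites were shared against 0.0429% by random placement. When each site was instead moved at random within 5 kb, 1.28% overlapped on average and 1.64% at most (permutation test, one-sided, p = 0.001), so the observed share was 16.7-fold above this local placement. The placement used genomic positions, so chance overlap within the same RNAs was not measured. With replicate 2 limited to its 16964 highest-scoring sites, 15.1% of replicate 1 sites were shared.

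From a score of 10 upwards, strong sites were shared far more often than weak ones. In replicate 1, 7.17% (interval 6.57 to 7.83) of sites with scores from 10 to 19 were shared, 46.7% (44.5 to 48.8) of those of at least 100 and below 500, and 75.7% (59.9 to 86.6) of the 37 sites with scores of at least 10000. In replicate 2 the corresponding shares were 2.08% (1.91 to 2.27), 25.8% (24.4 to 27.2) and 76.3% (60.8 to 87.0) of 38 sites. The 112 replicate 1 sites with scores from 5 to 9 went against this order, with 17.9% (11.9 to 26.0) shared, while the 3985 such sites of replicate 2 did not, with 1.18% (0.888 to 1.56). The median score of shared sites was 59 against 22 for unshared sites in replicate 1, and 56 against 18 in replicate 2.

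**Figure D1:**
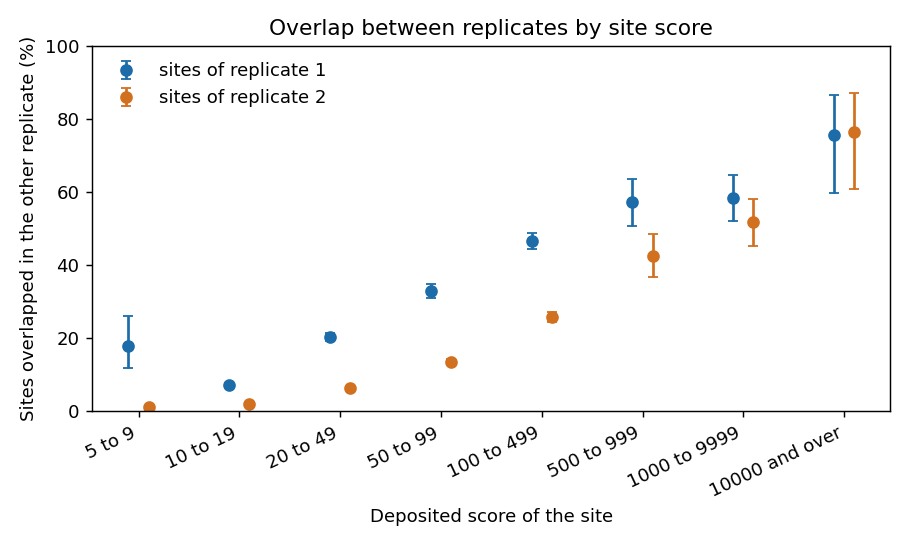
Percentage of sites overlapped by at least 1 nt on the same strand in the other replicate (y axis) by class of deposited score (x axis), for sites of replicate 1 and replicate 2; points are shares and bars 95% Wilson intervals. From the class 10 to 19 to the class 10000 and over, the share rose from 7.17% to 75.7% in replicate 1 and from 2.08% to 76.3% in replicate 2.

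Where sites were shared, their edges often lay close together. Among the 3636 overlapping pairs, 16.5% had the same start and 17.6% the same end, and 5.34% had both. Start and end are genomic here, so on the minus strand the start is the downstream edge of the RNA. Among overlaps produced by moving sites at random within 5 kb, 2.9% had the same start. These moves ignored the sequence, while RNase T1 cuts after guanosine, so edges expected to coincide from the sequence alone are not counted in this share. Starts lay within 2 nt of each other in 43.2% of pairs, and 77.1% of pairs overlapped by at least 50% of both sites. For these latter measures no random share was computed, so how far they exceed chance is not known.

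Sites of one replicate that lay near a site of the other were mostly on its strand. A replicate 2 site lay within 1 kb on the same strand for 53.1% (interval 52.4 to 53.9) of replicate 1 sites, and within 1 kb on the opposite strand for 3.96%. Within 10 kb the shares were 76.7% and 18.8%. Seen from replicate 2, 29.3% of sites had a replicate 1 site within 1 kb on the same strand and 1.69% on the opposite strand. Neighbouring sites within a list followed the same pattern. In replicate 1, 92.9% (91.5 to 94.0) of neighbours 100 to 1000 nt apart were on the same strand, 71.4% (70.3 to 72.5) of those 10000 to 100000 nt apart, and 49.1% (45.4 to 52.8) of those at least 1000000 nt apart. In replicate 2 these shares were 95.8%, 79.2% and 47.7%.

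**Figure D2:**
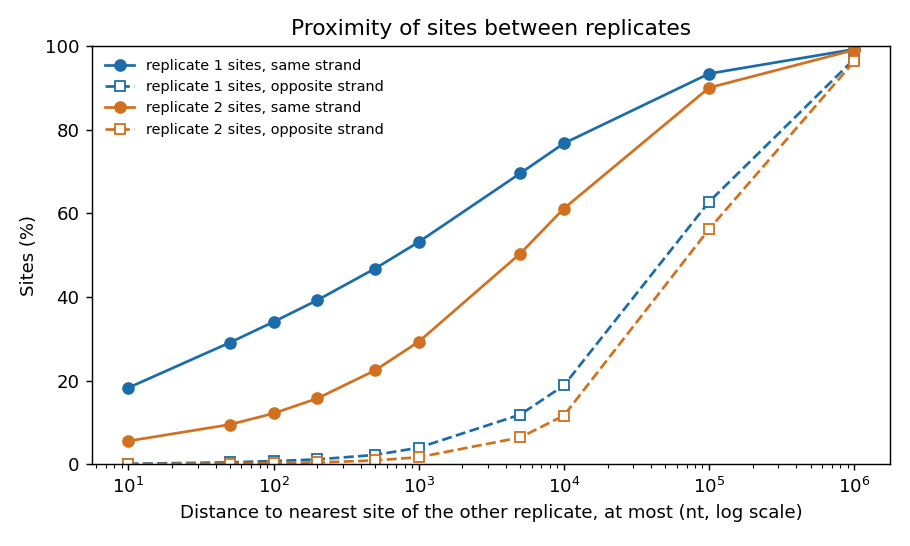
Cumulative percentage of sites (y axis) with a site of the other replicate within a given midpoint distance in nt (x axis, log scale), on the same strand (filled circles) or the opposite strand (open squares). Within 1000 nt, 53.1% of replicate 1 sites had a same-strand neighbour and 3.96% an opposite-strand one.

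Scores of shared sites were related. Across the 3621 replicate 1 sites with a partner, Spearman's rho was 0.68 and Pearson's r of the log10 scores was 0.76 (two-sided permutation p = 1e-05 for both, the smallest that 100000 resamples give). These are correlations across sites, and sites are not independent replicates. The log2 ratio of replicate 2 to replicate 1 score had a median of -0.21 and an SD of 1.37. In 12.3% of shared sites the scores differed by more than 4-fold.

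**Figure D3:**
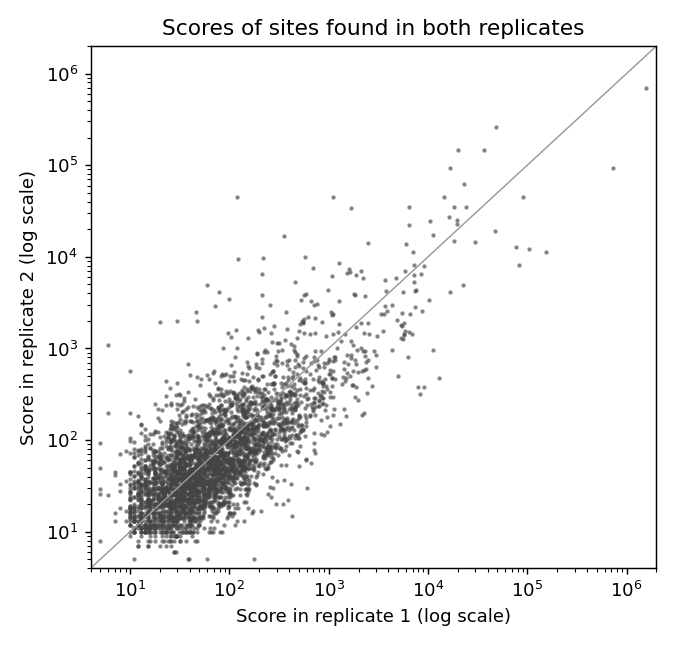
Score in replicate 1 (x axis, log scale) against score in replicate 2 (y axis, log scale) for the 3621 replicate 1 sites with an overlapping partner; each point is 1 site and the grey line marks equal scores. Spearman's rho was 0.68, and the site with the highest score in both lists stands at 1560568 and 702704.

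The strongest shared site lay on the plus strand of chromosome 6 (hg19) at 121007819 to 121007843 in replicate 1 and 121007817 to 121007841 in replicate 2. Both were 25 nt long and ranked first, with scores of 1560568 and 702704. The next lay on the plus strand of chromosome 2 at 27273706 to 27273729, with a score of 732404 in replicate 1, which was 7.89-fold that of its partner in replicate 2 (92813). A minus-strand site on chromosome 3 at 51728503 to 51728516 went the other way, with 48764 in replicate 1 and 263308 in replicate 2. The minus-strand site on chromosome 11 at 21022440 to 21022459 scored 16593 in replicate 1 and 92474 in replicate 2. The other chromosome 11 site, on the minus strand at 62609106 to 62609141, scored 24169 and 35020. A plus-strand site on chromosome 12 at 20704474 to 20704506 scored 23042 in replicate 1, inside a 76 nt site of replicate 2 with a score of 61989. The minus-strand site on chromosome 6 at 26305725 to 26305748 scored 47121 in replicate 1 and 19010 in replicate 2. The mitochondrial site at 6226 to 6241, on the plus strand, scored 91073 in replicate 1 and 44920 in replicate 2. The remaining pairs were on chromosome 21. With 1 value per library, none of these differences between replicates was tested.

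The chromosome 21 pairs lay in one stretch of the plus strand. Replicate 1 sites at 9827310 to 9827326 and 9827340 to 9827379 scored 36678 and 20207, and both fell inside the replicate 2 site at 9827309 to 9827384, which scored 145790. Between 9826065 and 9828459, replicate 1 had 11 sites and replicate 2 had 16 sites, which took 6.25% and 11.9% of the score sum of their lists. Of these, 9 sites of replicate 1 and 7 of replicate 2 were shared. The highest-scoring sites of the stretch did not overlap: the replicate 1 site at 9827099 to 9827124 scored 257599, and the replicate 2 site at 9827167 to 9827187 scored 291202. The longest site of either list, 412 nt, began here at 9826612 in replicate 2. The extent of this stretch was chosen after its values were seen.

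**Figure D4:**
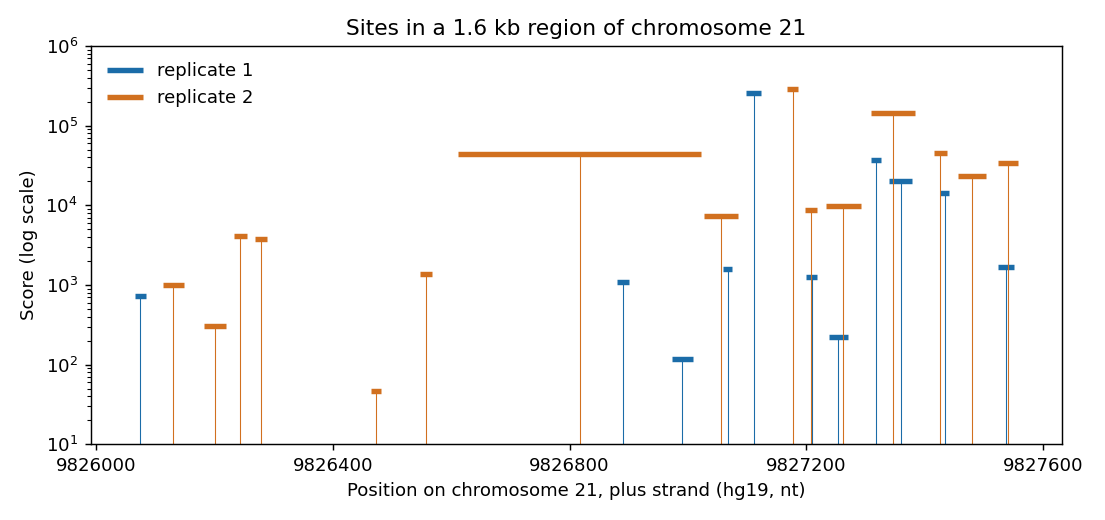
Sites of replicate 1 and replicate 2 on the plus strand of chromosome 21 (x axis, hg19 position in nt) by deposited score (y axis, log scale); horizontal bars span each site and thin lines drop from their midpoints. The highest bars, at 257599 in replicate 1 and 291202 in replicate 2, lie next to each other without overlap; 1 replicate 2 site further along, with a score of 16, is outside the plot.

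Site density followed the same order along the chromosomes in both lists at its upper end. Chromosome 19, the most gene-dense human chromosome, had the most sites per Mb of the nuclear chromosomes, with 20.2 in replicate 1 and 75.5 in replicate 2, and chromosome 17 followed with 15.0 and 57.4. Among the autosomes, the gene-poor chromosomes 13, 18 and 4 had the fewest, at 2.17, 2.35 and 2.63 sites per Mb in replicate 1 and 6.32, 6.49 and 6.26 in replicate 2. The share of sites per chromosome differed between the lists for 8 of the 25 chromosomes (Fisher's exact test, adjusted p under the threshold of 0.05). Chromosomes 16, 17, 19 and 22 held larger shares in replicate 2, with odds ratios of 1.24, 1.18, 1.15 and 1.19. Chromosomes 2, 4 and 6 and the mitochondrial chromosome held smaller shares, with odds ratios of 0.876, 0.716, 0.856 and 0.616. The smallest adjusted p was 3.6e-08, for chromosome 4, which held 2.97% of replicate 1 sites and 2.14% of replicate 2 sites. Sites on one transcript are not independent, so these p-values are too small.

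**Figure D5:**
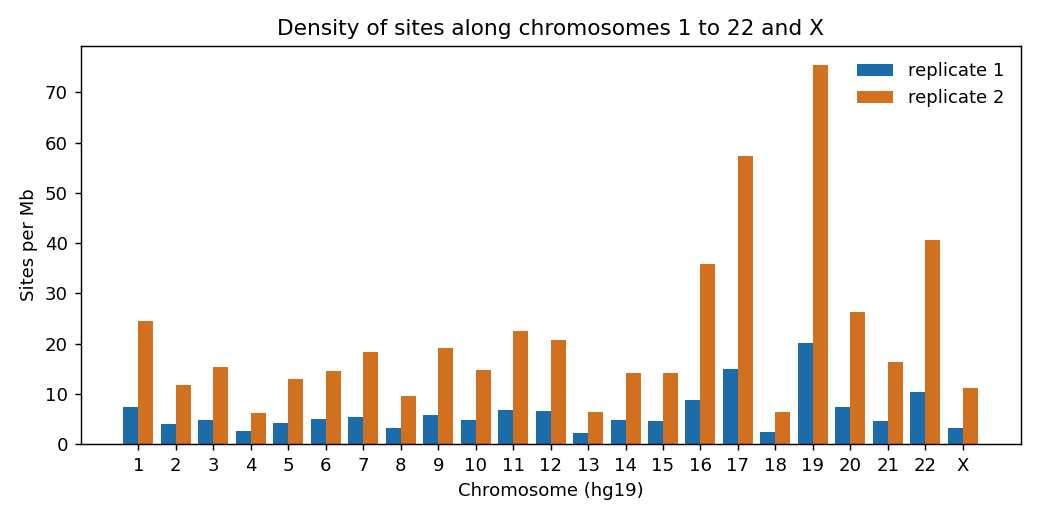
Sites per Mb (y axis) on chromosomes 1 to 22 and X (x axis) in replicate 1 and replicate 2, with the largest site end on each chromosome taken as its length. Chromosome 19 stands highest in both lists, at 20.2 and 75.5 sites per Mb.

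Mitochondrial RNA was represented in both lists. The mitochondrial chromosome held 92 sites in replicate 1 and 187 in replicate 2, which took 4.13% ± 0.357 (SD, n = 2) of the score sum. Its median site score was 193.5 in replicate 1 and 206 in replicate 2, against 26 and 19 for nuclear sites. The plus strand, whose sequence matches the mitochondrial ribosomal RNAs and the mRNAs other than ND6, held 68 sites in replicate 1 (73.9%, interval 64.1 to 81.8) and 120 in replicate 2 (64.2%, 57.1 to 70.7). It carried 97.0% and 88.6% of the mitochondrial score sum. Mitochondrial sites were shared more often than nuclear ones, with 57.6% (47.4 to 67.2) against 21.1% in replicate 1 (Fisher's exact test, two-sided, p = 3.5e-14) and 28.3% (22.4 to 35.2) against 6.42% in replicate 2 (p = 2.3e-20). Sites on one transcript are not independent, so the p-values of Fisher's test are too small. Sites are dense on this chromosome, and random placement on it gave 25.6% in replicate 1 and 12.6% in replicate 2 (permutation test, one-sided, p = 0.001 for both). Nuclear sites of the same score classes were shared at 44.4% in replicate 1 and 27.1% in replicate 2. The former lay just below the interval of the mitochondrial share, and the latter lay inside it.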

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

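The overlap between replicates stayed above every random placement (100 per alternative, 1000 for placement within 5 kb) under all 18 alternatives run. These were 9 settings, each seen from both replicates, so they are not independent checks. Apart from the 5 kb setting, sites were placed along the whole chromosome, which gave at most 0.715% and was a low bar. The size of the overlap moved with the lists compared. The share of replicate 1 sites was 16.5% with 50% of both sites required, 21.5% with strand ignored, 31.3% with gaps of up to 50 nt, 30.4% among sites at or above the median score of their list, 21.1% without the mitochondrial chromosome and, as the smaller list dictates, 6.51% with replicate 2 thinned at random. The share of replicate 2 sites ranged from 5.02% with 50% of both sites required to 20.8% among scores of at least 100. The restriction to scores of at least 100 in both lists (33.8% of replicate 1 sites) and to the highest scores of replicate 2 (15.1% of either list) were chosen after seeing the data. The correlation of scores stayed between 0.627, for scores below 1000 in both, and 0.677, for pairs with exactly 1 partner; the former and the removal of mitochondrial sites were also chosen afterwards. No sites of a list overlapped or touched on a strand, so merging removed none. Leaving out either replicate leaves no overlap to compute. For the share of score in the 10 strongest sites it gave 34.6% and 59.7%. No paired analysis was possible because the series has 1 group. The results on annotation classes, genes, gene lists and base composition, with their alternatives, were not run for want of a reference on the build of the lists. Depth is unknown, so how far it limits the overlap of weak sites was not settled.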

Other observations

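The tests of thinning to an equal score sum outside the 10 strongest sites and of placement within 5 kb were set down before their results were seen; the windows, the chromosomes and the other tests in this part were chosen afterwards. Some nuclear regions held many sites of 1 strand in both lists. Windows were ranked on each strand separately, so some excess over the opposite strand follows from the choice. Among windows of 100 kb, the plus strand of chromosome 16 from 2800001 to 2900000 had the best mean rank, with 19 sites in replicate 1 and 79 in replicate 2. The opposite strand of this window held 0 and 4 sites. Further along chromosome 16, the plus-strand window from 30700001 to 30800000 held 18 and 78 sites, with 2 and 3 on the opposite strand. The minus-strand window of chromosome 11 from 62300001 to 62400000 held 18 and 58 sites, and 9 of the former were shared; its opposite strand held 1 site in each list. The minus-strand window of chromosome 17 from 79800001 to 79900000 held 16 and 79 sites, of which 3 in replicate 1 were shared, and its opposite strand held 4 and 16.

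Chromosomes 16, 17, 19 and 22 together held 22.0% (95% Wilson interval 21.4 to 22.7) of replicate 1 sites and 25.8% (25.5 to 26.2) of replicate 2 sites. Among scores of at least 100 the shares were 21.9% (20.3 to 23.5) and 23.7%, with overlapping intervals, and among scores of at least 1000 they were 20.9% (16.5 to 26.2) and 15.0% (11.2 to 19.7). Sites of replicate 2 were also more clumped: 52.8% had another site of the list within 1 kb on the same strand, against 21.3% in replicate 1. After thinning replicate 2 to 16964 sites the share was 28.0% on average and 26.8% at least over 100 draws, while among the 16964 highest-scoring sites of replicate 2 it was 47.8%.

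Replicate 2 listed 3.29-fold more sites than replicate 1 at 0.968 times its score sum. Outside the 10 strongest sites, the score sum of replicate 2 was 1.57-fold that of replicate 1, outside the 100 strongest 1.89-fold and outside the 1000 strongest 2.70-fold. Deeper coverage of ordinary sites was a candidate explanation, although these sums include the additional sites and so partly restate their number. At the 3621 shared sites replicate 2 did not score higher, with a median log2 ratio to replicate 1 of -0.21. Of these sites, 2033 scored higher in replicate 1 and 1549 in replicate 2, but they are only the sites listed in both. Reading the score as a count, replicate 2 was thinned to the score sum of replicate 1 outside the strongest sites. With the sum outside the 10 strongest sites, the cut set beforehand, it kept 2.13-fold as many sites as replicate 1 at a score of at least 10, but the result depends on the cut: outside the 100 and 1000 strongest it kept 1.80-fold and 1.27-fold. At a score of at least 100 the same thinnings kept 0.918, 0.728 and 0.457 times as many sites as replicate 1, so none of them matched replicate 1 at both scores. Stronger thinning lowers both numbers, so this outcome followed from the numbers of sites by score and is not separate evidence. The thinning also takes both lists as complete from a score of 10, which is not known. It therefore does not decide on deeper coverage of all but the strongest sites, and a difference confined to weak sites stays open. The factors between the score scales that match the numbers of sites at scores of 10 and of 1000 differ 3.01-fold. This restates the numbers of sites by score: no single factor matches the lists at both scores. It does not exclude such a factor, because the match takes both lists as complete from a score of 10, which is not known. A difference in calling or in conversion rates between the libraries stays open: site names carry running numbers up to 248010 in replicate 1 and 235517 in replicate 2, of which 6.75% and 22.2% are listed, and no biological explanation was tested.

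Of the sites with scores of at least 10000, 9 in each replicate had no partner. One explanation is that the same RNA was cut at another place nearby. Of these 18 sites, 10 (55.6%, interval 33.7 to 75.4) had a same-strand site of the other replicate within 200 nt, 7 of 9 in replicate 1 and 3 of 9 in replicate 2. Of the 10, 3 were on the mitochondrial chromosome, where 92.3% of all unshared replicate 1 sites had such a neighbour, so they say little. On the nuclear chromosomes 7 of 15 had one (46.7%, 24.8 to 69.9), 4 of 6 in replicate 1 and 3 of 9 in replicate 2. Among all unshared nuclear sites the shares were 22.5% and 9.73%. Within each replicate the odds ratios were 6.89 and 4.64 (Fisher exact test, p = 0.026 and 0.049). Of the 7, those starting at 9827099 in replicate 1 and at 9827167 and 9827457 in replicate 2 lay in the dense chromosome 21 stretch. A near neighbour there says little, and sites of the same stretch are not independent, so these p-values are too small. For nuclear unshared sites with scores of at least 1000 and below 10000 the share was 62.0% (51.7 to 71.2) in replicate 1 and 34.3% (25.7 to 44.1) in replicate 2. In replicate 2 it was no higher at scores of at least 10000, with 33.3%. Over all sites, a same-strand site of the other replicate within 1 kb was also more common at high scores. From scores of 10 to 19 to scores of at least 10000 this rose from 32.2% to 97.3% in replicate 1 and from 19.2% to 92.1% in replicate 2. The higher share at high scores therefore does not tell a shift from local density. The intervals for the 18 and the 15 sites span 50%, so the shift stays open. Some sites without a near one lay not far past the cut of 200 nt, at 210, 309, 435 and 439 nt from the nearest site. The farthest was the minus-strand site of chromosome 5 at 109035454 to 109035467, with a score of 22521 in replicate 1. It lay 362464 nt from the nearest replicate 2 site. For such sites, reads shared between near-identical copies could not be tested without the genome sequence.

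Of the replicate 1 sites with a same-strand replicate 2 site within 1 kb, 40.2% (39.2 to 41.2) overlapped one, and from replicate 2 the share was 22.2% (21.5 to 22.8). Over all replicate 1 sites, 1.28% overlapped after placement within 5 kb, against 21.3% observed, which argues against chance overlap at that scale. The chance share among sites with a neighbour within 1 kb was not computed. Whether weak sites were sampled in only one of the libraries stays open. In replicate 2 the share fell with falling score, as this explanation needs, from 45.1% (43.2 to 47.0) for scores of at least 100 to 10.8% (9.95 to 11.7) for scores from 10 to 19 and 5.48% (4.14 to 7.21) for scores from 5 to 9. In replicate 1 it fell from 58.6% (56.5 to 60.7) to 22.3% (20.5 to 24.1), but was 29.4% (19.9 to 41.1) in the lowest class, whose 68 sites are too few to tell a rise from a fall. Fragments of abundant RNAs recovered without contact to SOX2 stay open too, since no control library was analysed here.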
